A study of Arabidopsis thaliana with 6 samples.

How the data were processed

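Total RNA of a mixotrophic Arabidopsis thaliana cell suspension, that is, cells grown on sugar in the light, was measured on 6 Affymetrix ATH1 arrays, 3 of cells given 75 µM phytoprostane A1 (PPA1) and 3 of cells given 0.5% methanol in water, all for 4 h. Per the labels, the 3 replicates of each treatment were independent; what made them so is not given in the sources used here, so p-values measure the spread between these samples, which may be partly technical. Groups and replicate numbers came from the sample titles. No methanol content is given for the PPA1 samples, so whether the control matched their solvent is not known here.

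The deposited values are intensities on a linear scale, made with GCRMA per the submitters' processing notes, with no version given in the sources used here. GCRMA corrects the background by probe sequence, normalizes between arrays and summarises the probes of a probe set. Its background model sets the smallest values, so a large fold change against a value near 1 intensity unit depends on that model. Array medians lay between 41.9 and 51 intensity units. The number of arrays limits the precision.

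The table held 22810 probe sets. The 64 control probe sets were never tested, which left 22746. Of these, 13513 had 1 gene name in the platform annotation, 503 had several and 8730 were not named there. The gene table of the TAIR10.1 assembly held 13436 of the 13513 and changed 0 names, and 11885 of these names are locus codes. No gene was named from a probe set with several genes, and no coordinates are given because no genome build is named for the values. The number of per-sample value columns left unused was 0.

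Values were taken to log2 as deposited. A probe set was tested if it lay above the 40th percentile of the array on at least 3 of the 6 arrays, which left 13924. PPA1 was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust variance, treatment as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. A log2 fold change is the mean log2 of PPA1 minus that of control, and its SE is the moderated one. On simulated arrays with 200 changed probe sets among 13924, the fit recovered 4% of 2-fold changes and 65% of 4-fold changes, with 3 false calls. The cutoff that the adjustment sets on p loosens as more probe sets change. The real comparison called 2293, so these shares do not carry over to it, though 2-fold changes may still be missed.

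Gene lists, 36 in all, were fixed before the data were examined, as were the test, the alternatives and the rule for named genes. A list with at least 5 tested members was tested with camera at a preset correlation of 0.01, adjusted over the 9 such lists, and again with camera at an estimated correlation and with fry. A gene with several probe sets was represented by the one with the highest mean. Counts of called members are given over all tested probe sets and adjusted over the list alone. The named genes were the 8 largest increases and the 8 largest decreases among probe sets with 1 gene name, an adjusted p under the threshold and all 3 PPA1 arrays on one side of all 3 control arrays, plus from each list the 2 called members with the largest change in the direction of most called members. The rule gave 36 genes. Other list members are named after their values were seen.

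The replicate numbers were checked for pairing. Deviations from the group means correlated at 0.166, 0.182 and 0.144 between arrays of the same number. Each array correlated best with its own number, for PPA1 replicate 3 by a small margin (0.144 against 0.115 with control replicate 2). How often chance would give this match was not tested. The numbers were taken to pair the arrays, on the evidence of the values and not of the labels. A batch was looked for in the spiked hybridisation controls, which averaged 8.58 (control) and 8.77 (PPA1) log2 units on the replicate 1 arrays and between 9.20 and 9.54 on the other 4. Replicate 1 was therefore treated as 1 batch and replicates 2 and 3 as another. The first batch holds 1 array per group and allows no test, and the second was fitted alone.

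Alternatives chosen before the data were examined were quantile normalization, median centring, no filter, a filter at the 60th percentile, a variance trend, robust variance, the replicate number as a block, each array left out in turn, log2(value + 16) and array weights, and, for lists, an estimated correlation, fry and all probe sets of a gene. Added after seeing the data were the batch as a block, the second batch alone and PPA1 replicates 2 and 3 averaged into 1 replicate. The 3′ to 5′ differences of control transcripts were compared by two-sided exact permutation tests, whose smallest p is 0.1 with 3 arrays against 3. The 25S ribosomal RNA signal was compared in the same way, a test added after seeing the data.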

Results

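Phytoprostane A1 is a cyclopentenone oxylipin that forms from linolenic acid without enzymes, by attack of free radicals, and the study asked how such a reactive oxylipin changes gene expression. Transcript levels of cultured Arabidopsis cells were measured after 4 h with 75 µM PPA1 (n = 3 arrays) or with 0.5% methanol as the control (n = 3 arrays). Median intensity lay between 49.7 and 51 units on the control arrays and between 41.9 and 44.8 on the PPA1 arrays. The first principal component, with 68.1% of the variance, placed the control arrays between -58.3 and -55.8, PPA1 replicates 2 and 3 at 77.8 and 79.7, and PPA1 replicate 1 between them at 12.5. On the second component, with 16.7%, PPA1 replicate 1 lay apart at 64.4. Control replicate 1 lay at 6.7 and the other arrays between -19.3 and -15.8. The position of 1 array does not decide whether PPA1 replicate 1 was a simple intermediate.

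With PPA1 the 4 tested heat shock genes rose and the 4 tested mitotic genes fell, and so did part of other lists: 7 of 20 genes of glycosyl transfer and 2 of 5 of glutathione conjugation rose, while 5 of 15 of cell wall loosening and 3 of 5 of auxin response fell. The latter 4 lists were called at a preset correlation between genes but not at an estimated one (adjusted p between 0.27 and 0.292). For glutathione conjugation and auxin response the estimates, -0.0486 and -0.000351, lay below the preset 0.01, so a higher correlation did not end those calls. Glutathione conjugation was not called within the batch of replicates 2 and 3 (0.306), nor auxin response without the filter (0.0675). In all, 882 of the 13924 tested probe sets rose and 1411 fell at an adjusted p under 0.05 (limma), of which 679 rose and 1009 fell at least 2-fold. In all of these 2293 the PPA1 arrays lay on one side of the control arrays, as did 40.3% of tested probe sets, where chance gives 10%. Of the 2293, 1056 had no single gene name. The share of increases among the calls depended on the scaling: it was 38.5% on the values as deposited and 60.6% (1342 up, 872 down) after median centring, which moved the median log2 change of all tested probe sets from -0.16 to 0.06. The counts also depended on single arrays. Without PPA1 replicate 1 they grew to 2192 up and 3373 down. They shrank to 364 and 583 without control replicate 1, 143 and 139 without control replicate 2, 379 and 640 without control replicate 3, 237 and 369 without PPA1 replicate 2, and 208 and 285 without PPA1 replicate 3. Within the batch of replicates 2 and 3 the counts were 2182 up and 3331 down, and with the batch as a block 1367 and 2066. These fits count PPA1 replicates 2 and 3 as separate replicates; the pair lay closer together than any other, so their independence is uncertain, and averaged into 1 replicate they gave 243 up and 379 down. Without the filter the counts were 184 and 226. The main fit had no replicate term. With the replicate number as a block the counts were 744 and 1123, and 1629 of these calls were among the 2293.

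Genes of xenobiotic conjugation were among the increases. Of 20 tested family 1 UDP-glycosyltransferases, which attach sugars to small molecules, 7 rose, 0 fell and 13 did not pass, and the 7 were also called when adjusted over the list alone. UGT73B5 went from 1.67 ± 0.73 to 6.63 ± 0.69 log2 units (SD, n = 3), a log2 fold change of 4.96 (SE 0.47, adjusted p = 0.00327). UGT71B8 changed by 4.03 (SE 1.07, adjusted p = 0.0474). UGT73B4 (3.33), UGT73B1 (2.56) and UGT87A2 (1.92) rose too. These 3 rose more in replicate pair 1 (5.5, 4.6 and 2.3) than in pairs 2 and 3 (2.2, 1.6 and 1.7), whereas UGT71B8 rose less (2.0 against 5.0). Of 5 tested tau class glutathione transferases, which join glutathione to electrophiles, 2 rose, also when adjusted over the list alone, and 3 did not pass. GSTU25 rose by 3.69 (SE 0.60, adjusted p = 0.0135) and GSTU22 by 2.44 (SE 0.33, adjusted p = 0.00812), while GSTU16 stood at 0.92 (adjusted p = 0.19), GSTU18 at -0.31 (0.439) and GSTU27 at -0.13 (0.853). The one tested member of the list of oxylipin reductases and stress-induced P450s, the alkenal reductase gene AER, rose by 1.89 (SE 0.20, adjusted p = 0.00423), also over the list alone. As a list, the glycosyltransferases were shifted up (camera, adjusted p = 0.00494; adjusted p = 0.27 with an estimated correlation). The median of the glycosyltransferases was 0.39, but 0.63 without control replicate 3, 0.14 within the batch of replicates 2 and 3, 0.16 without the filter and 0.06 with a filter at the 60th percentile. The filter left out 31 of the 51 named members, of which, fitted without it, 18 lay above 0 and 13 below, and 1 passed. The tau class transferases were shifted up too (adjusted p = 0.0361; adjusted p = 0.27 with an estimated correlation). The call of the tau class list ended within the batch of replicates 2 and 3 (adjusted p = 0.306), with the batch as a block (0.0502), after median centring (0.0739), with array weights (0.151) and without control replicate 1 (0.123) or PPA1 replicate 1 (0.134, median 0.44 against 0.92). UGT71B8 lost its call with log2(value + 16) (adjusted p = 0.0522) and when any single array other than PPA1 replicate 1 was left out (up to 0.146). GSTU22 lost it without control replicate 2 (0.0521). UGT73B5 changed by 2.58 with log2(value + 16).

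All 4 tested heat shock genes rose, also when adjusted over the list alone, a list too short for a camera test. ATHSP22.0, a small heat shock protein gene, rose by 5.94 log2 units (SE 0.77, adjusted p = 0.00694). HSA32, which acts in acquired heat tolerance, went from 7.20 ± 0.25 to 11.84 ± 1.49 log2 units (SD, n = 3), a change of 4.64 (SE 0.68, adjusted p = 0.0103). AT5G48570, an FKBP type immunophilin gene, rose by 3.26 (adjusted p = 0.0187) and Hsp70-2 by 1.21 (adjusted p = 0.043, near the threshold). On PPA1 replicate 1 the level of ATHSP22.0 was 10.31 against 12.84 and 12.85 on replicates 2 and 3, and that of HSA32 was 10.12 against 12.76 and 12.64. HSA32 lost its call without control replicate 2 (adjusted p = 0.0586). None of the 6 tested genes of protein folding in the endoplasmic reticulum passed by either adjustment (camera, adjusted p = 0.389). BZIP60, a transcription factor gene of the unfolded protein response, stood at 0.83 (adjusted p = 0.154). Among 11 autophagy genes 2 rose and 9 did not pass, by both adjustments. ATG8H rose by 2.14 (SE 0.31, adjusted p = 0.00974) and ATG8B by 0.73 (SE 0.18, adjusted p = 0.0393). Both encode ubiquitin-like proteins of the autophagosome. The autophagy list was shifted up (camera, adjusted p = 0.0268; adjusted p = 0.292 with an estimated correlation), but not after quantile normalization (0.0761), within the batch of replicates 2 and 3 (0.0689) or without control replicate 1 (0.108). ATG8B lost its call with the replicate block (adjusted p = 0.0703) and when any single array other than PPA1 replicate 1 was left out (up to 0.155), and ATG8H lost it without control replicate 2 (0.0576).

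**Figure D1:**
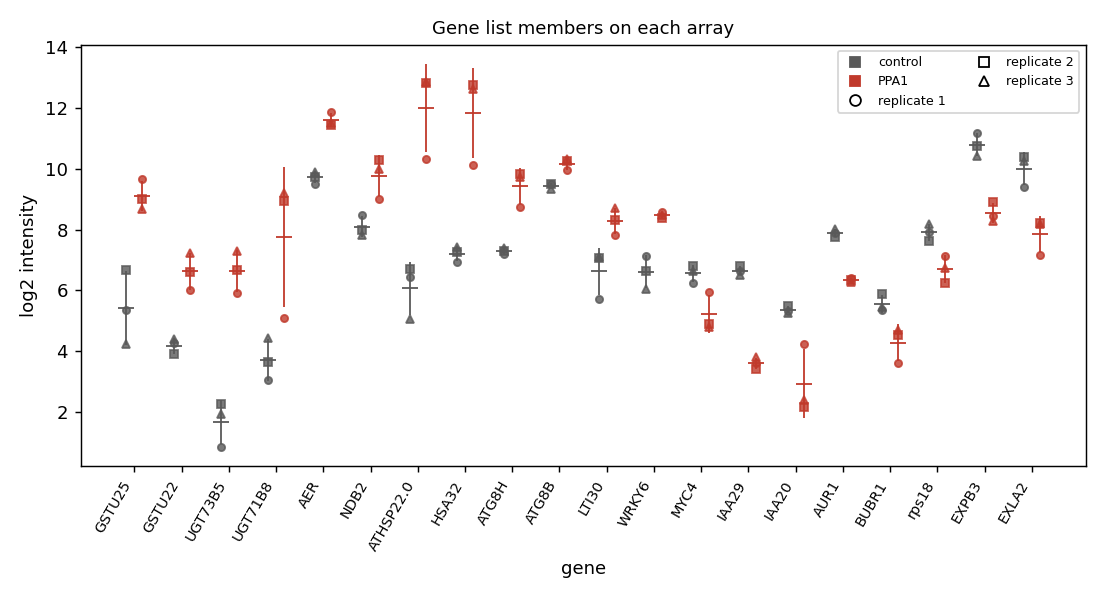
Log2 intensity (vertical axis) of the 20 genes named from the gene lists (horizontal axis) on each array, with control in grey and PPA1 in red, marker shapes for replicates, and bars for the mean and SD (n = 3). The PPA1 arrays lie on one side of the control arrays for each gene, and PPA1 replicate 1 lies nearer to the controls than replicates 2 and 3 for ATHSP22.0 (10.31 against 12.84 and 12.85).

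Mitotic and cell wall loosening genes were among the decreases. The 4 tested mitotic genes fell, also over the list alone, a list too short for a camera test. The Aurora kinase gene AUR1 had a log2 fold change of -1.55 (SE 0.17, adjusted p = 0.00423). AUR2 had one of -1.24 (adjusted p = 0.0275) and AUR3 one of -0.69 (adjusted p = 0.0464, near the threshold). The spindle checkpoint gene BUBR1 had one of -1.28 (SE 0.33, adjusted p = 0.0435). The 2 tested genes of DNA replication did not pass by either adjustment, nor did the 4 tested core histone genes over all probe sets, of which 2 were higher when adjusted over the list alone. Of 15 tested expansin and xyloglucan endotransglucosylase genes, whose products loosen the cell wall, 5 fell (6 adjusted over the list alone), 0 rose and 10 did not pass. EXPB3 fell from 10.79 ± 0.38 to 8.54 ± 0.34 log2 units (SD, n = 3), a change of -2.25 (SE 0.27, adjusted p = 0.00578). EXLA2 changed by -2.16 (SE 0.39, adjusted p = 0.0181) and XTH19 by -2.04. That list was shifted down (camera, adjusted p = 0.0184; adjusted p = 0.292 with an estimated correlation), with a median of -1.35 that was -0.79 with log2(value + 16) and -0.77 without the filter. BUBR1 lost its call after median centring (adjusted p = 0.0783), after quantile normalization (0.0969), with a variance trend (0.0532) and when any single array other than PPA1 replicate 1 was left out (up to 0.154). EXLA2 lost it without control replicate 2, control replicate 3 or PPA1 replicate 3 (up to 0.0878). BUBR1 changed by -0.82 with log2(value + 16).

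Auxin response genes had a median change of -2.44 over 5 tested members, of which 3 fell by both adjustments and 2 did not pass. IAA29 went from 6.65 ± 0.13 to 3.60 ± 0.18 log2 units (SD, n = 3), a change of -3.05 (SE 0.18, adjusted p = 0.00196). IAA20 changed by -2.44 (SE 0.53, adjusted p = 0.0276) and IAA30 by -1.99. These genes encode Aux/IAA proteins, repressors of auxin signalling. WES1, which encodes an enzyme that joins auxin to amino acids, stood at -3.28 (SE 1.39, adjusted p = 0.141). The list was shifted down (camera, adjusted p = 0.0121; adjusted p = 0.27 with an estimated correlation, and 0.0675 without the filter, where its median was -0.77). With log2(value + 16) the median was -1.35. The filter left out 7 of the 12 members, of which 0 passed without it (limma; 1 at an unadjusted p under 0.05). One of the 7, GH3.3, named after its values were seen, went the other way: it lay at 2.95, 9.32 and 9.75 log2 units on PPA1 replicates 1, 2 and 3 and at 1.15, 3.43 and 4.40 on the control arrays, a change of 4.35 (SE 2.01, adjusted p = 0.261 without the filter). IAA20 lost its call when any single array other than PPA1 replicate 1 was left out (adjusted p up to 0.11), and changed by -1.21 with log2(value + 16).

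Stress hormone and defence lists held few named members. MYC4, a transcription factor gene of jasmonate signalling, fell, with a log2 fold change of -1.35 (SE 0.34, adjusted p = 0.0405), while MYC3 stood at 0.13 (adjusted p = 0.741). The call of MYC4 held over the list alone. The dehydrin gene LTI30 rose by 1.66 (SE 0.43, adjusted p = 0.0428), 1 of 3 tested genes of abscisic acid and dehydration response by both adjustments. NDB2, which encodes an alternative NADH dehydrogenase of mitochondria, rose by 1.67 (SE 0.37, adjusted p = 0.0285), also over its list, of which it was the one tested member. Of 5 tested WRKY transcription factor genes WRKY6 rose by 1.87 (SE 0.29, adjusted p = 0.0117) and 4 did not pass, and 2 rose over the list alone. The list's median was -0.14 (0.07 after median centring, and -0.33, -0.04 and -0.06 without PPA1 replicate 1, 2 or 3) and its mean 0.39, and camera put it up without a call (adjusted p = 0.401). MYC4, LTI30 and NDB2 lost their calls when any single array other than PPA1 replicate 1 was left out (adjusted p up to 0.146, 0.142 and 0.113), and WRKY6 without control replicate 2 (0.0627). With the replicate block the adjusted p was 0.0735 for MYC4 and 0.0584 for NDB2, and MYC4 lost its call after median centring (0.0568) and quantile normalization (0.0531).

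The ribosomal protein list matched 15 genes, all encoded in the plastid genome, so it says nothing of cytosolic ribosomes. Of 13 tested, rps18 fell, with a log2 fold change of -1.21 (SE 0.28, adjusted p = 0.0329), 12 did not pass, and 6 were lower when adjusted over the list alone. The list was shifted down (camera, adjusted p = 0.0184; adjusted p = 0.485 with an estimated correlation), but not without PPA1 replicate 2 (0.0581). rps18 lost its call after median centring (adjusted p = 0.0532) and when any single array other than PPA1 replicate 1 was left out (up to 0.106). None of the 10 tested photosynthesis genes, of which psaI, psaJ and psbT are plastid genes, passed by either adjustment (camera, adjusted p = 0.408).

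No tested member passed by either adjustment in the lists of MATE and ABC transporters (1 tested), glutathione and sulfate assimilation (3), antioxidant enzymes (3), the 26S proteasome (1), jasmonate biosynthesis (1), ethylene (1), phenylpropanoid and monolignol biosynthesis (2), flavonoid biosynthesis (1), sugar starvation (2) and xylem markers (1). The transporter list does not stand for all MATE genes. AT5G38030, a MATE efflux carrier gene under a locus code, was not matched by it and rose by 6.02 (limma, adjusted p = 0.0127). Over all 14 lists with tested members and no call in limma, 6 of 38 members had an unadjusted p under 0.05. They were 2 core histone genes, 2 photosynthesis genes, 1 gene of folding in the endoplasmic reticulum and 1 of sulfate assimilation. Among all 13924 tested probe sets 5008 had such a p, a larger share. The lists of phi class glutathione transferases, salicylate and systemic defence, D-type cyclins and CDK inhibitors, senescence and cell death, root hair markers and guard cell markers had named members but 0 above the filter. TGA factors, tryptophan and camalexin biosynthesis and seed markers had 0 named members and were not analysed here.

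**Figure D2:**
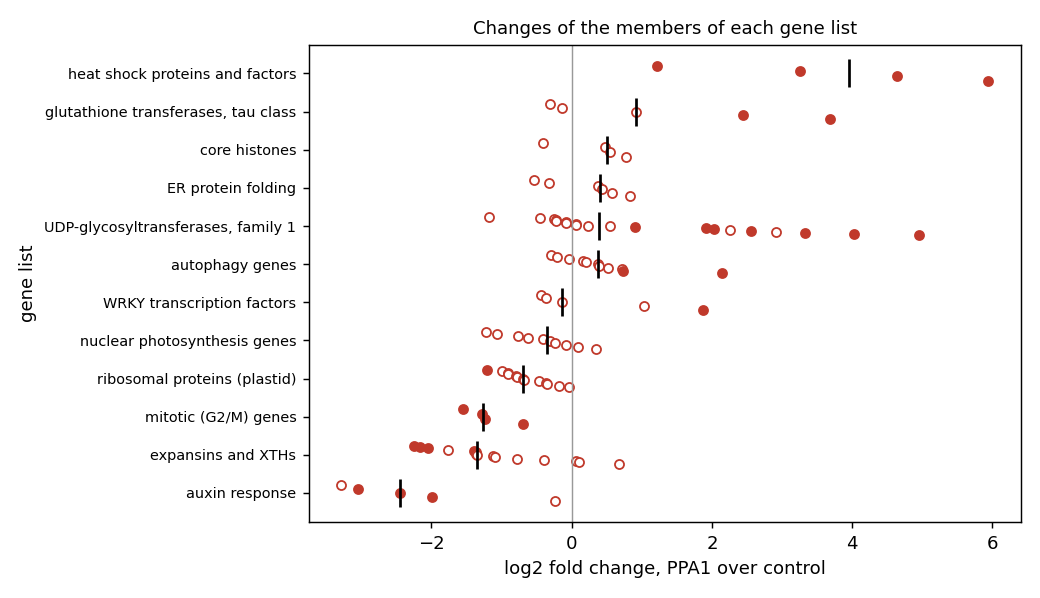
Log2 fold change of PPA1 over control (horizontal axis) of each tested member of the gene lists with at least 4 tested members (vertical axis), filled where the adjusted p was under 0.05, with a black bar at the list median. The 4 heat shock genes lie between 1.21 and 5.94, and the 4 mitotic genes between -1.55 and -0.69.

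Among the changed probe sets with 1 gene name and the groups apart, which leaves out the 1056 without a single name, the largest increases were as follows. AT4G31615 rose by 6.46 (SE 1.51, adjusted p = 0.0334), AT1G68620, an alpha/beta hydrolase gene, by 6.41 (SE 0.48, adjusted p = 0.00229), AT1G09500 by 6.32 (SE 0.50, adjusted p = 0.00263) and AT1G30700, of the berberine bridge enzyme family, by 6.30 (SE 0.43, adjusted p = 0.00218). AT3G26450 (6.11), AT4G26820 (6.04), AT1G12030 (6.03) and AT5G38030, a MATE efflux carrier gene (6.02), followed. The largest decreases were in AT1G33760, an ERF type transcription factor gene, at -5.85 (SE 0.39, adjusted p = 0.00218), AT5G45700 (-4.96), AT3G17120 (-4.45), AT3G28420 (-4.12), AT3G16280 (-3.97), AT3G07000 (-3.95), AT1G27620, of an acyltransferase family (-3.94), and AT1G64450 (-3.93). These sizes and their order depended on the handling of low values: with log2(value + 16), the 8 increases lay between 2.41 (AT1G30700) and 4.87 (AT5G38030) and the 8 decreases between -2.74 (AT1G64450) and -1.40 (AT3G16280), with AT1G33760 at -2.22 and AT5G45700 at -1.55. AT4G31615, AT4G26820, AT1G12030, AT3G28420 and AT1G64450 lost their calls when any single array other than PPA1 replicate 1 was left out (adjusted p up to 0.127). AT3G17120 lost it without control replicate 1, 2 or 3 or PPA1 replicate 2 (up to 0.106). AT5G38030 and AT3G16280 lost theirs without control replicate 2 (0.0681 and 0.053), and AT1G12030 and AT1G64450 also with the replicate block (0.052 and 0.0523). Of the 36 named genes, 15 kept their calls whichever single array was left out, and within the batch of replicates 2 and 3 all 36 were called. With PPA1 replicates 2 and 3, which lay close together, averaged into 1 replicate, 13 of the 36 lost their calls.

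Signs of RNA quality were compared between the groups, and no difference passed the test, which could not have reached 0.05 with 3 arrays against 3. The 3′ to 5′ log2 difference was 0.77 ± 0.08 in control and 0.85 ± 0.06 in PPA1 for actin (SD, n = 3, exact permutation p = 0.2). It was -0.06 ± 0.05 and -0.12 ± 0.08 for GAPDH (exact permutation p = 0.4). For ubiquitin it was 0.06 ± 0.11 and -0.03 ± 0.11 (exact permutation p = 0.3). The smallest two-sided p is 0.1. The signal for 25S ribosomal RNA, compared after the data were seen, was 12.38, 11.56 and 11.66 log2 units on control replicates 1, 2 and 3 and 12.32, 10.39 and 10.37 on PPA1 replicates 1, 2 and 3 (exact permutation p = 0.3). PPA1 replicates 2 and 3 were closer to each other than any other pair of arrays, with an SD of their log2 differences of 0.351 against 0.491 to 0.675 between control arrays. PPA1 replicate 1 differed from them with an SD of 0.916 and 0.908.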

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

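The tests of this part were chosen after the data were seen. Among 19 Arabidopsis control probe sets, which were not tested in the comparison, 6 lay higher on all 3 PPA1 arrays than on all 3 control arrays. All 5 for the housekeeping enzyme GAPDH were among them, at log2 differences of 0.851, 1.27, 0.967, 0.892 and 0.953, together with 1 for ubiquitin at 0.88 (n = 3 arrays per group, exact permutation p = 0.1 for each, the smallest possible). The 6 for actin lay lower on all PPA1 arrays, at log2 differences between -0.927 and -0.52. The number of probe sets above and below stayed at 6 and 6 after median centring and after quantile normalization.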

How the results depend on the processing

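The batch as a block, the second batch alone and the averaging of PPA1 replicates 2 and 3 were chosen after the data were seen. No named gene changed direction in any refit. The PPA1 arrays of these genes lay on one side of the control arrays, so only median centring and quantile normalization could have reversed them. No tested list changed its camera direction either, but the median of the WRKY list went from -0.14 to 0.07 after median centring. Not every result could be refitted: the filter at the 60th percentile kept only 19 of the 36 named genes and 6 of the 9 lists. UGT73B5, GSTU22 and IAA20 were among the genes it left out. The auxin, tau class and WRKY lists were not tested under it. Of the refits run, 509 of 631 for named genes and 166 of 186 list tests kept their side of the threshold as well. The counts did not. Main counts were 882 up and 1411 down, 679 and 1009 at least 2-fold. Median centring gave 1342 up and 872 down (651 at least 2-fold lower). Without the filter, 184 rose and 226 fell, all at least 2-fold, of 22746 tested. Array weights gave 3286 and 5461 (1440 and 2079), with a weight of 0.156 for PPA1 replicate 1. The batch block gave 1367 up, and the second batch alone 2182 and 3331 (1400 and 2027). PPA1 replicates 2 and 3 averaged into 1 gave 243 and 379, all at least 2-fold. Leaving out 1 array gave 143 to 2192 up and 139 to 3373 down (143 to 1353 and 139 to 1914), highest without PPA1 replicate 1 and lowest without control replicate 2. The replicate block gave 744 up and 1123 down (655 and 952), within 1.5 times of the main counts; 1629 of its calls were among the 2293. It ended the calls of 5 named genes and changed no call of a list.

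With an estimated correlation no list was called. The estimate lay below the preset 0.01 for tau class transferases (-0.0486) and auxin (-0.000351), so a higher correlation did not end those calls. The medians do not depend on the test and are those of the report. They were 0.38 for autophagy, -2.44 for auxin, -1.35 for expansins and xyloglucan endotransglucosylases and 0.92 for tau class transferases. They were -0.70 for plastid ribosomal proteins (also lost with directional fry) and 0.39 for glycosyltransferases. Where a call ended, list medians were 0.34 (autophagy, quantile normalization) and 0.22 (autophagy, second batch), -0.77 (auxin, no filter), and for tau class transferases 0.92 (array weights and batch block), 1.13 (median centring) and 0.52 (second batch). Leaving out 1 array gave 0.15 to 0.49 for autophagy, 0.44 to 1.25 for tau class transferases, -0.80 to -0.55 for plastid ribosomal proteins and 0.27 to 0.63 for glycosyltransferases (highest without control replicate 3). Medians of lists that stayed called moved too: for glycosyltransferases to 0.60 (median centring), 0.16 (no filter), 0.14 (second batch) and 0.06 (stricter filter), for auxin to -1.35 and for expansins to -0.79 with log2(value + 16), for expansins to -0.77 without the filter, for autophagy to 0.59 (median centring) and 0.22 (PPA1 replicates 2 and 3 averaged), and for tau class transferases to 1.42 (no filter). Mixed fry, which asks whether members change in either direction, called endoplasmic reticulum folding (median 0.40; 0.74, 0.24 and 0.23 without PPA1 replicate 1, 2 or 3) and WRKY genes (median -0.14; -0.33, -0.04 and -0.06). Robust variance was run for counts and genes, not for lists. Without the filter 19 of 36 named genes lost their calls, and with PPA1 replicates 2 and 3 averaged 13 did. The cause of these differences was not tested. Low signal limits the largest fold changes, which shrank with log2(value + 16) while 35 of 36 calls remained.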

Other observations

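The lists of small heat shock protein and kinesin loci and of plastid genome genes, and the tests of PPA1 replicate 1 and of other splits of the arrays, were chosen after the data were seen. Of 9 tested loci of small heat shock proteins, chaperones that hold unfolding proteins, 7 rose, 0 fell and 2 did not pass (8 up adjusted over the list alone), with a median log2 fold change of 4.83 (camera, adjusted p = 6.94e-08; adjusted p = 0.145 with an estimated correlation). AT2G29500 rose by 5.94 (SE 0.31, adjusted p = 0.00148) and AT1G53540 by 5.94 (SE 0.33, adjusted p = 0.00153), each higher on 3 of 3 PPA1 arrays than on any control array. AT1G52560 stood at 5.72 (SE 1.98, adjusted p = 0.091) and AT5G54660 at -0.62 (adjusted p = 0.258). ATHSP22.0 belongs both to this list and to the heat shock list of the report.

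Of 24 tested loci of kinesins, the motor proteins of microtubules, 10 fell, 0 rose and 14 did not pass (13 fell adjusted over the list alone), with a median of -0.97 (camera, adjusted p = 0.000602; adjusted p = 0.181 with an estimated correlation). AT2G28620 changed by -3.39 (SE 0.64, adjusted p = 0.0196), ZCF125 by -2.06 (SE 0.48, adjusted p = 0.0329) and KINESIN-13A by -0.92 (SE 0.16, adjusted p = 0.0174). On PPA1 replicates 1, 2 and 3, AT2G28620 lay at 3.7, 1.0 and 2.2 log2 units and ZCF125 at 4.6, 2.6 and 4.0. The sizes of these 2 changes depend on the handling of such low values. The median difference of the kinesin loci was -0.96, -0.80 and -0.92 in replicate pairs 1, 2 and 3, whereas that of the small heat shock protein loci was 3.16, 5.84 and 5.68. Of 63 tested plastid genome genes 2 fell and 0 rose (0 and 0 adjusted over the list alone), with a median of -0.37 (camera, adjusted p = 0.0328; adjusted p = 0.655 with an estimated correlation). After median centring and after quantile normalization the medians were 5.04 and 4.84 for small heat shock proteins (7 up, 0 down in both), -0.76 and -0.81 for kinesins (7 and 6 down) and -0.16 and -0.38 for plastid genes (0 and 3 down). In the batch of replicates 2 and 3 alone, 8 small heat shock protein loci rose and 1 fell, 14 kinesin loci fell, and 12 plastid genes fell and 1 rose. With the replicate block 7 small heat shock protein loci rose, 11 kinesin loci fell, and 1 plastid gene rose and 1 fell. With log2(value + 16) 7 small heat shock protein loci rose, 12 kinesin loci fell and 4 plastid genes fell, with medians of 4.59, -0.69 and -0.35.

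PPA1 replicate 1 changed less than replicates 2 and 3 over the tested probe sets as a whole, though not in every gene. The SD of the log2 differences between PPA1 and control was 0.881 in pair 1, against 1.18 and 1.2 in pairs 2 and 3. Over 990 probe sets changed at least 4-fold in replicates 2 and 3, the slope of the pair 1 difference on the pair 2 difference was 0.461 (95% bootstrap interval over probe sets, which are not independent, 0.432 to 0.492). That of pair 3 on pair 2 was 0.964 (0.94 to 0.985), but the choice of these probe sets by their change in pairs 2 and 3 favours it. Over all 13924 tested probe sets, with no choice by size, the slopes were 0.451 and 0.905. A slope also falls where genes change in another pattern, so it does not measure size alone. An equal log2 shift of both replicate 1 arrays would cancel within the pair, so these values argue against that. A shared effect that scales the changes would not cancel, and the slopes cannot speak on it. The spiked hybridisation controls were lower on both replicate 1 arrays. Control RNA mixed into PPA1 replicate 1 would leave 1 share of the linear change for all genes, but the median share was 15.9% (13.7 to 18.5) among the 524 that rose and 50.7% (42.4 to 55.4) among the 466 that fell, and 11.5% of the risers changed as much as in replicates 2 and 3 or more; this argues against mixing as the whole cause. Among list members that rose at least 2-fold in replicates 2 and 3, the median share was 67.5% for 11 detoxification genes and 15.8% for 10 heat shock genes. Shares of the detoxification genes ran from 2.17% to 383%. Of them 45.5% changed as much as in replicates 2 and 3 or more, against 0% of the heat shock genes. On log2 the contrast was smaller. The median was 2.36 in pair 1 against 2.78 in pairs 2 and 3 for detoxification, and 3.18 against 5.63 for heat shock. This difference between the lists was not tested, since these genes were measured on 1 array pair and are not independent. Degraded RNA in PPA1 replicate 1 stays open, as 2 of 3 control transcripts had a 3′ to 5′ difference within the range of the other 5 arrays and actin lay just above it (0.901 against up to 0.874). The 25S ribosomal RNA signal followed the same pattern, with pair differences of -0.07, -1.17 and -1.29 log2 units, but was also higher on control replicate 1 than on the other control arrays (12.38 against 11.56 and 11.66); it does not decide between these explanations. A biological difference, such as cells that met a lower effective dose or an earlier stage of the response, may also account for the pattern and was not tested.

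Between other splits of the 6 arrays into 3 and 3 the highest number of changed probe sets was 0, against 2293 in the real split and 1688 at least 2-fold; 1 of the 10 splits, the real one, gave as many. At an unadjusted p under 0.05 (limma) the other splits gave 19 to 1443 probe sets and the real one 5008, with the highest of the others in the split that sets control replicates 1 and 2 with PPA1 replicate 1 against the rest. With 10 splits the share cannot fall under 0.05. Of the 4 splits that part all 3 replicate pairs, the other 3 each gave 0 adjusted calls and 22 to 970 unadjusted ones; each of these sets arrays of both treatments together on both sides.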
